A study of Homo sapiens with 3 samples.

How the data were processed

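Per the labels' protocols, total RNA of HT-29 cells was extracted on columns, treated with DNase and made into Illumina sequencing libraries. There were 3 libraries, 1 per group, and groups were taken from the sample labels: CCICs (adherent, bright for CD24 and CD44), Non-CCICs (adherent, dim for both) and Colonospheres (suspension, serum-free medium). Reads were aligned with BWA 0.7.3 to the hg19 genome, per the submitters' processing notes. The counting tool, its strand setting and the selection of RNA by poly(A) tail or depletion are not given in the sources used here.

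The authors deposited 1 table of 26861 RefSeq transcript records (24237 coding, 2624 non-coding) with a raw read count and a log2 value per library. The table lists records whose highest count among the libraries is 100 or more; the lowest such maximum is 100. The deposited log2 values equal the log2 of the count times 1 factor per library, which was 1.48 for CCICs, 1 for Non-CCICs and 1.07 for Colonospheres, with no scaling for transcript length. The listed totals would give factors of 1.48, 1 and 1.59. The Colonospheres factor thus does not follow from its listed total, and the table does not account for the gap. This factor lowers every Colonospheres value alike, so differences from that library are also given relative to the library medians. In Colonospheres, 5 counts are blank, and the log2 value there is that of a count of 1. Record starts are counted from 0 in the table and were written here from 1. The table's coordinates follow hg19, and no reference annotation of another build was used for them.

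Of 14086 gene symbols, 5929 had several records. The ratio of the highest to the lowest record within a symbol had a median of 1.10, and 83.7% of these symbols stayed within 1.5-fold, so isoform records largely share reads. Each symbol was represented by the record with the highest mean, and a total over all records counts reads more than once. The expression floor was the median over genes of the mean log2 value, 10.46, which equals 1410 normalized reads and left 7043 genes. No sample column of the table was left unused.

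Differences are differences of deposited log2 values between 2 libraries, and a gene counted as different at 2-fold or more. No test between groups is possible with 1 library per group. Counting error per gene was given as an exact Clopper-Pearson 95% interval of the 2 counts, scaled by the deposited factors. For 33 gene lists (800 genes), the median difference over the measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Lists with fewer than 5 measured members were not ranked. A list was said to stand apart below the 2.5 or above the 97.5 percentile, as a description of these libraries. Overlap was set beside n1 × n2 / N. A planned random reassignment of each gene's values among the 3 libraries was run but not used, because it moves the Colonospheres difference into the control library and so does not give a count without effect.

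Genes were named by a rule. Above the floor, it took the 12 largest differences in each direction for CCICs against Non-CCICs, 10 for Colonospheres against Non-CCICs and 6 for Colonospheres against CCICs. CD44, CD24 and RBM5 were always taken, and up to 4 members of each list with the largest differences. Some genes that the rule takes are not reported here. Genes outside the rule are said to be chosen after their values were seen, except where they illustrate an overlap or a gene ontology term. The groups, comparisons, lists, rule and most alternatives were fixed before the data were examined. These alternatives were no floor, a floor at the 75th percentile, centring of each library on its median, quantile normalization, 1 added before the logarithm, summed records per symbol, and list members above the floor only. Alternatives chosen after seeing the data were scaling of the counts to the listed totals and TMM scaling in edgeR 4.0.16. Coding records on whole chromosomes only, and removal of a trend with transcript length, were also chosen then. That trend was the median in each of 20 length bins over all genes, list members included. A separate trend, fitted on genes outside each list, was used in the tests of explanations at the end and where stated. The lists without CD44, CD24, BIRC5 or the host genes, and lists of RNAs without poly(A) tails and of polyadenylated histone variants, were also added then.

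The steps were tested on simulated counts for CCICs against Non-CCICs with an assumed noise SD of 0.2 on the log2 scale. Over 7043 genes, the 2-fold rule took 8% of genes changed 1.5-fold, 90% of those changed 2.5-fold, 100% of those changed 4-fold or 8-fold, and 0% of unchanged genes. Of 200 unchanged lists, 7% fell outside the central 95% of their random lists. All these shares depend on the assumed noise, which no replicate could check. The rate of false calls in the real libraries is therefore not known. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3.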

Results

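RNA was sequenced from HT-29, an established human colon carcinoma line, in 3 libraries, 1 for each of 3 groups. The CCICs library came from adherent cells sorted as bright for both CD24 and CD44, and the Non-CCICs library from adherent cells sorted as dim for both. The Colonospheres library came from cells grown in suspension without serum. The listed read counts summed to 93110759 in CCICs, 137761485 in Non-CCICs and 86490240 in Colonospheres; a read that falls in several isoforms of a gene is counted in each. Of 14086 genes, 7043 lay at or above the expression floor. With 1 library per group, no difference has a replicate check and no p-value is given. Intervals in square brackets are exact binomial 95% limits for counting error only and leave out variation between libraries. Reads are not independent molecules, so these limits may be too narrow even for counting error. Gene coordinates are those of the hg19 transcript records.

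The first comparison set the double-bright against the double-dim adherent cells. The series' title concerns the long non-coding RNA LUST, the self-renewal of CCICs and Wnt/beta-catenin signalling. The sort markers came first, as a check on the labels. CD44, a hyaluronan receptor (chromosome 11, 35160417 to 35253949), had 7420 reads in CCICs and 2803 in Non-CCICs, which was 3.92-fold higher in CCICs (log2 difference 1.97 [1.91, 2.03]). CD24, a surface glycoprotein, had 75317 and 36268 reads and was 3.07-fold higher (1.62 [1.60, 1.64]); it has near-identical copies in the genome between which reads can be split. Both differences had the direction of the sort labels, and both were also at least 2-fold with each library centred on its median. The LUST transcript, which is antisense at the RBM5 locus, was not analysed here. RBM5 itself, an RNA-binding splicing regulator (chromosome 3, 50126341 to 50156397), differed by 0.21 [0.14, 0.28] between the sorted cells, and strand was not stated, so reads of an antisense partner cannot be told from its own.

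Of the 7043 genes, 100 were at least 2-fold higher and 81 at least 2-fold lower in CCICs, so that 55.2% of them were higher. With TMM scaling, chosen after seeing the data, 77 were higher and 95 lower, a share of 44.8%. The gene furthest above was ANXA13, an intestinal annexin (chromosome 8, 124693034 to 124749647), with 1339 against 116 reads and a log2 difference of 4.09 [3.82, 4.38]. CLEC3A, a C-type lectin, followed at 3.09 [3.04, 3.14]. CFTR, the epithelial chloride channel (chromosome 7, 117120017 to 117308718), had 28445 against 5207 reads, a difference of 3.01 [2.97, 3.06]. AKR1B10, an aldo-keto reductase, was 2.98 higher [2.82, 3.13], though it has close paralogs. Phospholipase PLD1 was 2.85 higher, the inhibitory G-protein subunit GNAI1 2.78, the connexin GJB1 2.58, the growth factor receptor FGFR3 2.46, creatine kinase CKB 2.36, and the sulfate-activating enzyme PAPSS2 2.09. HNF4A, a transcription factor of intestinal and hepatic epithelium (chromosome 20, 43029896 to 43061485), was 2.25 higher [2.10, 2.40].

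On the other side, the ribosomal RNA precursor RNA45S5 had 10470 reads in CCICs and 265784 in Non-CCICs (−4.10 [−4.13, −4.07]). It is a repeated locus recorded on an unplaced contig. The pseudogene PI4KAP1, which shares sequence with its parent gene, stood at −2.32. RARRES1, a retinoid-responsive membrane protein, and TERC, the telomerase RNA (chromosome 3, 169482398 to 169482848), both stood at −2.26. PTGS2, the inducible cyclooxygenase, was at −2.17 [−2.25, −2.08], the palmitoyltransferase ZDHHC2 at −2.10 and the calcium-binding protein S100P at −2.00. Other lower genes named by the rule encode short transcripts, among them RPS29 (−2.23), RPS21 (−2.13), ROMO1 (−2.10) and the small Cajal body RNA SCARNA2 (−2.06). Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. RNA without a poly(A) tail, a list added after seeing the data, lay 0.34 below its random lists here (percentile 0.02). Of its 26 members, 17 were lower and 9 higher. How RNA was selected is not given, so unequal recovery of such RNA between the 2 libraries cannot be told from a group difference.

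**Figure D1:**
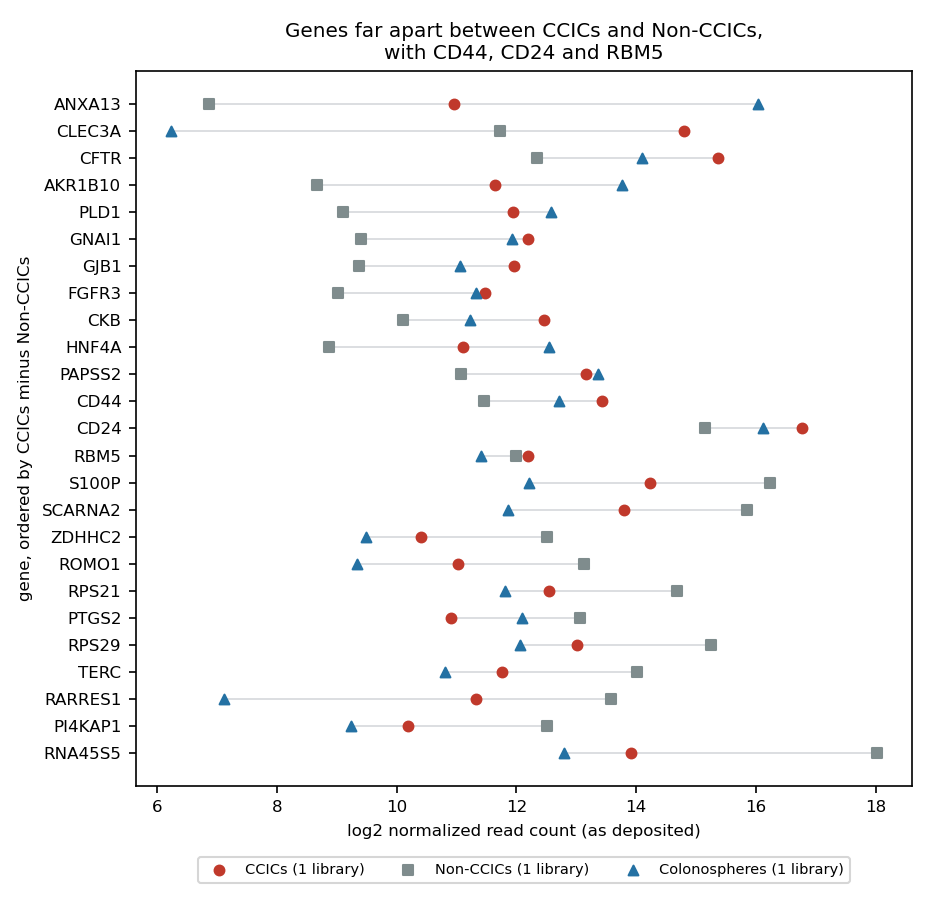
Each row is a gene and each mark is 1 library, placed on the horizontal axis at its log2 normalized read count as deposited; rows are ordered by CCICs minus Non-CCICs. ANXA13 is the top row with a difference of 4.09 and RNA45S5 the bottom row with −4.10, while RBM5 lies near the middle with 0.21.

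The list of G2/M phase genes had a median above all of its random lists in CCICs. Of 29 measured G2/M phase genes, 28 were higher, 6 of them at least 2-fold, and the list median was 0.83 against 0.04 for random lists of the same size and expression (percentile 100 of 10000 lists). The phosphatase CDC25C was 1.40 higher [1.31, 1.49], the kinesin CENPE 1.26, topoisomerase TOP2A 1.24 [1.22, 1.26] and the spindle protein NUSAP1 1.06. The 27 S phase genes had a median of 0.10 (percentile 77.6), with RRM2 and RRM1 both at 0.45. Replication-dependent histones had a median of 0.29 over 41 genes (percentile 100). Of these, 2 were at least 2-fold higher, HIST1H4D (1.24) and HIST1H2BH (1.04), and 1 was lower. Histone genes are near-identical copies, so reads can be split among them.

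Stem cell markers and Wnt target genes had medians above those of their random lists, and both lists contain the sort marker CD44. Both also hold LGR5, ASCL2, EPHB2, EPHB3, RNF43, ZNRF3 and SOX9, so their results are not independent of each other. For 21 measured intestinal and colon cancer stem cell markers the median was 0.33 (percentile 99.9), with 4 at least 2-fold higher and 1 lower. Without CD44 and CD24, a comparison chosen after seeing the data, the median of the other 19 was 0.22, at percentile 97.4 and inside the central 95% of random lists. ALDH1A1, an aldehyde dehydrogenase, was 0.94 higher [0.92, 0.96] and the adhesion molecule ALCAM 0.84. SOX9, a crypt transcription factor, stood at −0.76 [−0.87, −0.64]. LGR5, the crypt stem cell receptor, had 346 reads in CCICs and 1108 in Non-CCICs, a log2 difference of −1.11; it lies below the expression floor and was chosen after its values were seen. The 28 Wnt/beta-catenin target genes had a median of 0.37 (percentile 99.96), and 6 were at least 2-fold higher and 1 lower. Without CD44 and BIRC5, a comparison also chosen after seeing the data, the other 26 stood at percentile 99.92. Matrilysin MMP7 was 1.74 higher [1.68, 1.81], the cotransporter SLC12A2 0.62 and MYC 0.40, while AXIN2, a feedback inhibitor of the pathway also chosen after its values were seen, stood at 0.12. Below the floor and chosen in the same way, DKK1 had 870 reads against 126 (3.35) and SP5 419 against 72 (3.11). Over the 13 targets at or above the expression floor, the list lay 0.12 above its random lists, at percentile 90.5. The 34 Wnt pathway components had a median of −0.06 (percentile 4.97), with none at least 2-fold higher and 1 lower, and with a length trend removed the list stood at percentile 1, below the central 95%. Among them, TLE1 was at 0.64, APC at 0.47 and FZD6 at −0.35.

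Lists of absorptive and secretory colon cell markers also had medians above those of their random lists in CCICs. The median of 18 colonocyte differentiation genes was 0.34 (percentile 99.5), with 6 at least 2-fold higher and none lower. The brush border protein VIL1 was 1.76 higher [1.70, 1.82], the peptidase DPP4 1.56 and the mucin MUC13 1.40. Quantile normalization placed that list at percentile 91. For 14 goblet cell markers the median was 0.44 (percentile 99.9), with 10 higher and 4 lower, but 1 in each direction at least 2-fold and only 3 at or above the floor. The disulfide isomerase AGR2 stood at 0.87 and GALNT12 at 0.73, whereas the mucin MUC2 (−0.34) and the trefoil peptides TFF3 (−0.35) and TFF2 (−1.29), chosen after their values were seen, were lower. Only 2 enteroendocrine markers were measured, with a median of −0.75. Cholesterol and sterol synthesis genes had a median of 0.22 over 22 genes (percentile 99.3), with STARD4 at 0.63 and FDFT1 at −0.39. The 8 immune cell markers had a median of 0.58 (percentile 99.2), but 7 of them lay below the floor, and LYZ, the abundant one, which intestinal cells also express, stood at −0.06. For 4 endothelial markers, all below the floor, the median was 0.60, and for 7 fibroblast markers, also below it, −0.04 (percentile 21.7).

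NF-kB target, interferon-stimulated, p53 target, and immediate early and heat shock lists had medians below those of their random lists in CCICs. Of 16 NF-kB targets and chemokines, 15 were lower, 2 of them at least 2-fold (median −0.57, below all random lists). The chemokine IL8 stood at −1.74 [−1.82, −1.66] and the inhibitor NFKBIA at −0.93, whereas NFKBIZ was 0.40 higher. Over the members at or above the floor alone, this list lay at percentile 3.42. Interferon-stimulated genes had a median of −0.29, with 22 of 24 lower, 2 of them at least 2-fold, namely IFI6 (−1.25) and IFI27 (−1.18). The p53 target genes had a median of −0.41, with 15 of 16 lower and 3 at least 2-fold lower, which were the BH3-only gene BBC3 (−1.65 [−1.74, −1.56]), the death receptor TNFRSF10B (−1.10) and the cell-cycle inhibitor CDKN1A (−1.04). Immediate early and heat shock genes had a median of −0.21 over 22 genes (percentile 0.09), with MAFF at −1.46 and DUSP1 at −0.86. Quantile normalization moved them to percentile 3.36.

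Lists of the translation and respiration machinery had medians below those of their random lists in CCICs. The 72 cytosolic ribosomal protein genes had a median of −0.38, with 62 lower and 6 at least 2-fold lower. The 48 nuclear oxidative phosphorylation genes had a median of −0.29, with 35 lower, 3 of them at least 2-fold (NDUFA1 −1.61, COX6C −1.11, NDUFA4 −1.02). Both medians lay below all random lists, and both lists hold short transcripts, with median lengths of 709 and 1102 bases against 2997 over all genes. With a length trend fitted on genes outside each list removed, the ribosomal list moved from −0.43 to −0.16 relative to its random lists. The oxidative phosphorylation list moved from −0.34 to −0.10 (percentile 1.72). Across genes outside these lists, the 2677 in the shortest of 5 length classes had a median difference of −0.06 and the 2817 in the longest 0.12. Epithelial genes had a median of −0.11 over 25 genes (percentile 1.96), although E-cadherin CDH1 was 1.00 higher; SPINT2 stood at −0.83 and ELF3 at −0.79. The 21 transcripts of the RBM5 locus and cancer lncRNA list had a median of −0.25 (percentile 0.04), with none at least 2-fold higher and 4 lower. They included NEAT1 (−1.23) and GAS5 (−1.02), and without the protein-coding genes of the list the median was −0.34.

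Of the 28 lists with enough measured genes, 8 lay above and 8 below the central 95% of their random lists. If genes varied independently, 1.4 lists would lie outside. Members of a list can vary together and some lists share genes, so the gap to 1.4 does not measure an excess over chance. The remaining 12 lay between −0.16 and 0.13 of their random lists. Besides S phase genes, Wnt pathway components and fibroblast markers, these were the Notch pathway, mesenchymal genes, fatty acid synthesis, hypoxia response and glycolysis. The unfolded protein and integrated stress response, TGF-beta and BMP response, ERK output, and the ABC transporter and xenobiotic list were also among them. Single members still differed. S100A4 stood at −1.88, the hypoxia-inducible carbonic anhydrase CA9 at 1.70, the stress transcription factor DDIT3 at −1.52, the phosphatase DUSP4 at −1.33 and the BMP target ID2 at 1.26. The 4 measured pluripotency factors had a median of 0.27. No mitochondrially encoded transcript was analysed here.

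**Figure D2:**
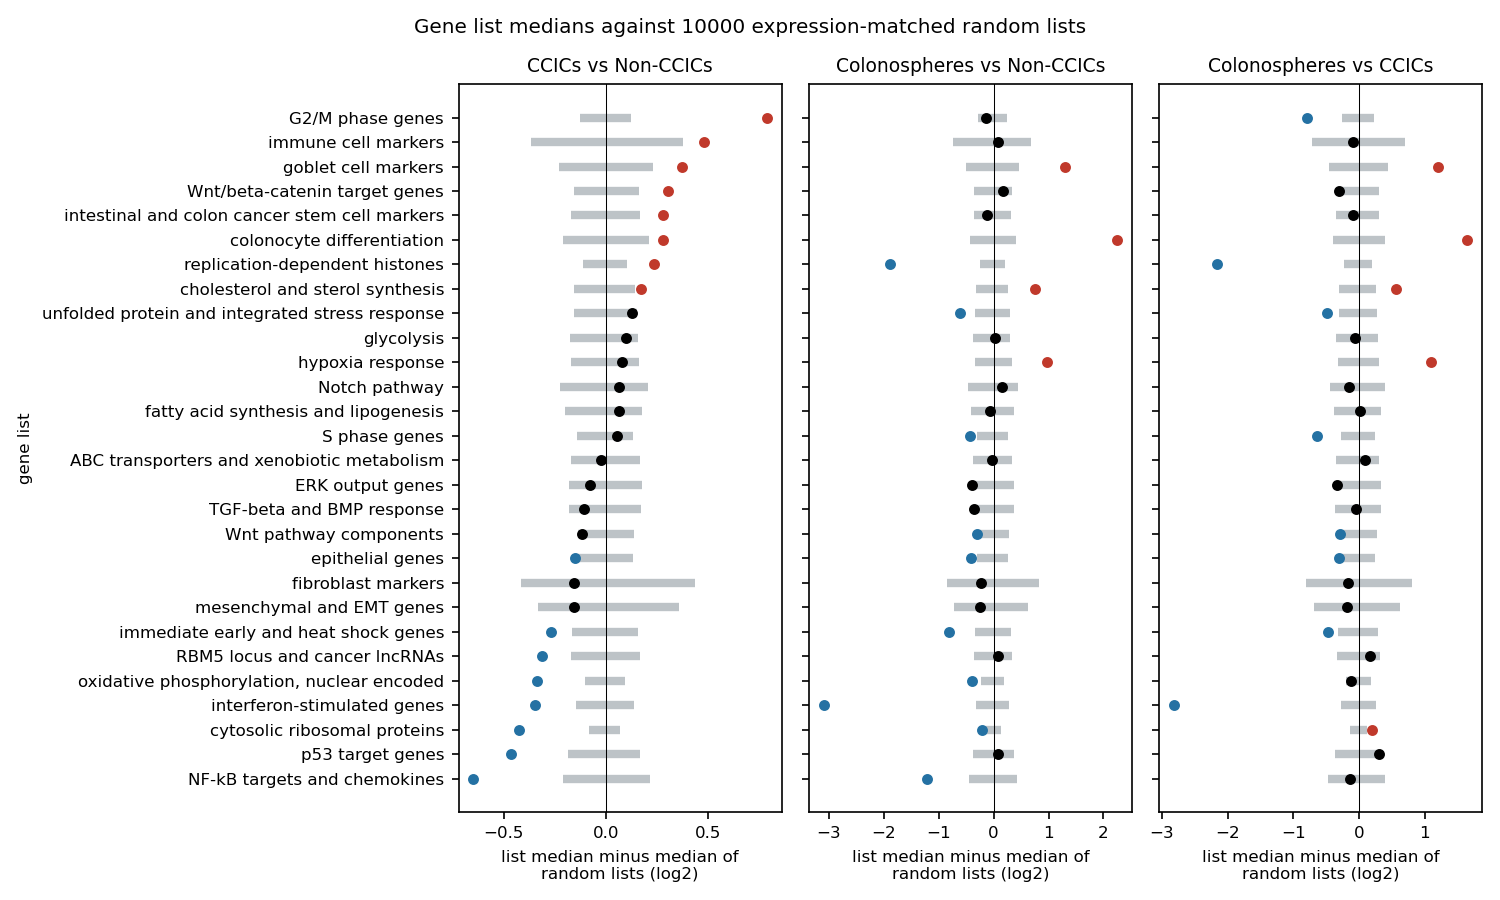
Each row is a gene list and each panel a comparison; points show the list median minus the median of 10000 expression-matched random lists (log2), and grey bars the central 95% of those lists. Red points lie above that range, blue points below it and black points inside it. G2/M phase genes are the top row of the first panel at 0.79, and interferon-stimulated genes reach −3.10 and −2.82 in the Colonospheres panels.

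Colonospheres were next set against Non-CCICs, which differed in the sort, the medium and the mode of growth at once. As deposited, 100 genes were at least 2-fold higher and 1981 lower, but the median gene also stood at −0.62. With each library centred on its own median, 380 genes were higher and 627 lower, so that the share of higher genes among those called went from 4.81% to 37.7%. Gene values for Colonospheres are therefore given relative to the library medians, and list positions relative to expression-matched random lists. ANXA13 had 62873 reads in Colonospheres and 116 in Non-CCICs, a log2 difference of 9.87 (9.19 [8.92, 9.46] as deposited). AKR1B10 was 5.77 higher, the proteoglycan CSPG4 4.87, the hypoxia-responsive gene NDRG1 4.86, HNF4A 4.36, DPP4 4.18, PLD1 and FAM105A both 4.16, and AGR2 4.08. The kinase gene MAP3K12 had 10894 against 1174 reads. The median half-width of the counting interval among the genes named by rule was 0.08, and the widest was 0.35, for CLEC3A.

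Interferon-stimulated genes were the most distant list. All 24 were at least 2-fold lower as deposited and 23 of them after centring, and the list lay 3.10 below its random lists. IFI44L had 77 reads in Colonospheres and 21974 in Non-CCICs, a difference of −7.37. IFI6 stood at −5.45, IFI27 at −5.30 and IFI44 at −4.72. Among other genes, transglutaminase TGM2 stood at −6.99, RARRES1 at −5.78, the growth-factor-binding protein IGFBP6 at −5.64, the lysyl oxidase LOXL4 at −5.47, TNFAIP2 at −5.44, CLEC3A at −4.80 and LY6E at −4.77. NF-kB targets and chemokines lay 1.21 below their random lists, with 9 of 16 at least 2-fold lower after centring. Immediate early and heat shock genes lay 0.81 below theirs, with 9 of 22 at least 2-fold lower and 1 higher after centring. The immediate early genes MAFF and DUSP1 stood at −2.67 and −2.30. The higher gene, chosen after its values were seen, was the heat shock gene HSPA8, with 283326 reads in Colonospheres and 174142 in Non-CCICs. The joint list of the unfolded protein and integrated stress response lay 0.62 below. After centring, 5 of its 22 genes were at least 2-fold lower and 0 higher, with DDIT3 at −2.29 and CEBPB at −1.21.

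Lists of colon differentiation genes lay above their random lists in Colonospheres. The colonocyte list lay 2.25 above its random lists, with 12 of 18 genes at least 2-fold higher and 1 lower after centring, MUC13 at 3.06 among them; CEACAM1 stood at −1.98. Goblet cell markers lay 1.29 above, with 7 of 14 at least 2-fold higher, including SPDEF at 1.58, and 2 lower, SPINK1 and CREB3L1, both below the floor and chosen after their values were seen; 3 of the 14 lay at or above it. Hypoxia response genes lay 0.97 above, with 9 of 20 at least 2-fold higher, including the collagen prolyl hydroxylase P4HA1 at 2.30, and 2 lower; DDIT4 stood at −1.14. Cholesterol synthesis genes lay 0.75 above, with 11 of 22 at least 2-fold higher, including HMGCS1 at 1.54, and 1 lower; the regulator SREBF2 stood at −0.81.

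Replication-dependent histones lay 1.89 below their random lists, with 37 of 41 at least 2-fold lower after centring and HIST1H2BJ at −3.35. RNA without a poly(A) tail, a list added after seeing the data, also lay below, by 0.73 (percentile 0.04), with 6 of its 26 members at or above the floor. S phase genes lay 0.42 below (percentile 0.32), with UHRF1 at −1.29 and MCM5 at −1.28. Epithelial genes lay 0.41 below (percentile 0.38), with 5 of 25 at least 2-fold lower and 2 higher after centring; ELF3 stood at −3.15, and the higher genes, chosen after their values were seen, were the desmosomal protein DSP and CDH1. Oxidative phosphorylation genes lay 0.40 below, Wnt pathway components 0.30 below (percentile 2.17) and ribosomal protein genes 0.21 below (percentile 0.38). Removal of a length trend over all genes, list members included, reversed the ribosomal protein list to 0.14 above its random lists. The same removal moved oxidative phosphorylation to percentile 9.40. Such a trend can take up part of a list's own difference. Wnt components above the floor lay at percentile 10.2. The sort markers were both higher in Colonospheres, CD44 by 1.93 and CD24 by 1.66. The stem cell marker list was at percentile 26.6, with 7 of 21 genes at least 2-fold higher and 5 lower after centring, and Wnt target genes at 85.3, with 4 of 28 higher and 7 lower. PROM1, the gene of CD133, stood at −3.41, ZNRF3 at −1.87 and MMP7 at −2.37, whereas 2 genes chosen after their values were seen were higher, ALDH1A1 with 113155 reads in Colonospheres against 59692 and EPHB3, below the floor, with 1043 against 288. RBM5 stood at 0.11 after centring and −0.57 as deposited, so its sign depended on the scaling. In all, 4 lists lay above, 10 below and 14 inside the central 95%. The lists inside ranged from −0.39 to 0.18 of their random lists and included G2/M phase genes, p53 targets and glycolysis.

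**Figure D3:**
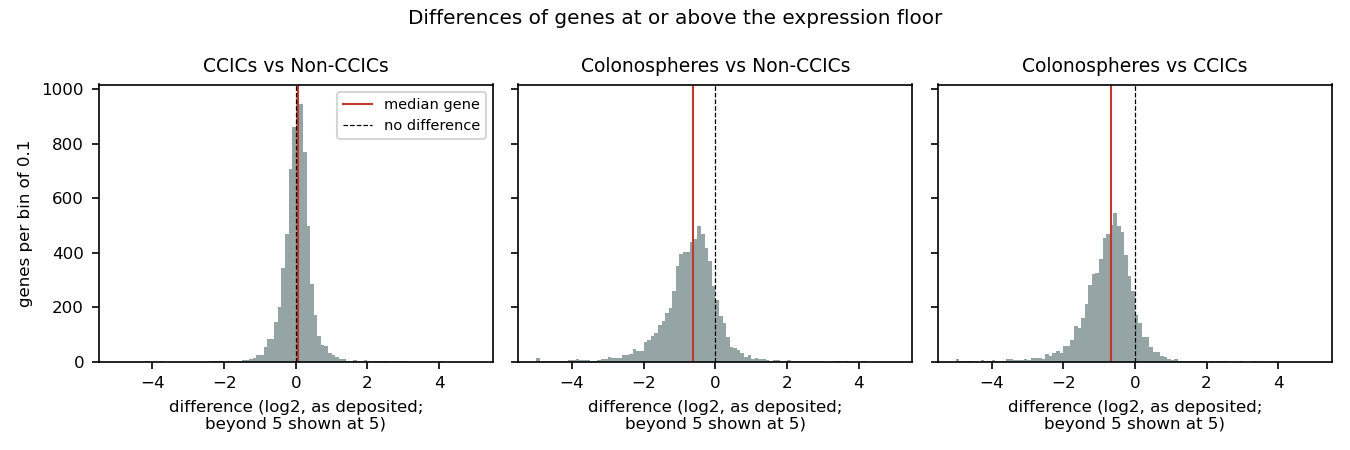
Histograms of the deposited log2 difference for the 7043 genes at or above the expression floor, with 1 panel per comparison and the number of genes per bin on the vertical axis. The red line marks the median gene, at 0.05 for CCICs against Non-CCICs and at −0.62 and −0.67 for Colonospheres against Non-CCICs and CCICs; the dashed line marks no difference.

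Colonospheres were last set against CCICs. As deposited, 48 genes were at least 2-fold higher and 2046 lower with the median gene at −0.67, and after centring 332 were higher and 476 lower. Among genes at or above the floor, ANXA13 was again furthest above at 5.81, followed by MAP3K12 and AKR1C1 (both 4.07), NDRG1 (4.06), the fatty acid transport protein SLC27A3 (3.65) and AGR2 (3.25). CLEC3A, which had been among the highest genes of CCICs, had 70 reads in Colonospheres and 19372 in CCICs (−7.86). IFI44L stood at −6.56, TGM2 at −6.05, TNFAIP2 at −5.31, IGFBP6 at −4.61 and gamma-synuclein SNCG at −4.57. CD44 and CD24 were close to level, at 0.00 and 0.08 relative to the library medians, and RBM5 stood at −0.07.

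The 3 cell cycle lists lay below their random lists in Colonospheres against CCICs. Replication-dependent histones lay 2.16 below their random lists, with 40 of 41 at least 2-fold lower after centring. G2/M phase genes lay 0.80 below and S phase genes 0.64 below, each under all random lists, although 4 of 29 and 7 of 27 genes were at least 2-fold lower after centring; UBE2C stood at −1.73, TOP2A at −1.12 and GINS2 at −1.17. Interferon-stimulated genes lay 2.82 below, with OAS3 and OAS2 both at −4.33. Lower lists also included the unfolded protein and integrated stress response (−0.49) and immediate early and heat shock genes (−0.47). Epithelial genes (−0.31, percentile 1.64, and 2.90 with the records of a symbol summed) and Wnt pathway components (−0.30, percentile 1.78) were lower as well. Colonocyte genes (1.65), goblet markers (1.21), hypoxia response (1.10), cholesterol synthesis (0.56) and ribosomal proteins (0.19, percentile 99.9) lay above. Quantile normalization moved the ribosomal list to percentile 69.8, and Wnt components above the floor lay at percentile 6.67. Stem cell markers (percentile 30.9) and Wnt target genes (percentile 3.58) were inside, but quantile normalization placed the latter below, at percentile 1.55. PROM1 stood at −3.88 and MMP7 at −4.08. The remaining 13 lists were also inside.

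Genes that differed in both CCICs and Colonospheres from Non-CCICs were counted. After centring, 53 genes were at least 2-fold higher in both, where independent lists of these sizes would share 4.59, and 59 were lower in both, against 7.83. As deposited, the counts were 44 and 67, against 1.42 and 22.8. After centring, the shared higher genes included ANXA13, AKR1B10, CFTR, CD44, DPP4 and CA9. The shared lower genes included BBC3, CDKN1A and DDIT3. Also among them were RNA45S5, TERC, SCARNA2 and RPPH1, and genes of short transcripts such as RPS29, RPS21, ROMO1 and NDUFA1. Both comparisons use the same Non-CCICs library, so the lists are not independent, and how much of the excess comes from that library was not determined.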

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

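TMM scaling, scaling to the listed totals, coding records and the length trend were chosen after seeing the data. In Colonospheres, deposited and centred values differed in part through the deposited scaling factor. Under scaling to the listed totals, the median gene stood at −0.06 against Non-CCICs and −0.10 against CCICs. For Colonospheres against Non-CCICs, the genes at least 2-fold higher and lower then numbered 296 and 754, and against CCICs 203 and 664. Centring each library gave 380 and 627, and 332 and 476, so scaling to the listed totals lay between the deposited and the centred counts. Quantile normalization gave 356 and 610, and 279 and 466, and TMM gave 386 and 620, and 358 and 449. For CCICs against Non-CCICs, centring moved the counts from 100 higher and 81 lower to 85 and 88. With no floor, the higher and lower counts were 487 and 240 for CCICs against Non-CCICs, 395 and 4840 for Colonospheres against Non-CCICs, and 264 and 5188 for Colonospheres against CCICs. With the floor at the 75th percentile they were 41 and 39, 39 and 835, and 20 and 873, and the genes shared between both comparisons with Non-CCICs numbered 14 higher and 28 lower. Those counts cover more or fewer genes, and the mix of calls also changed. For CCICs against Non-CCICs, the share of higher genes among those called was 55.2% as deposited. It was 67.0% with no floor and 51.25% with the floor at the 75th percentile. Over members above the floor only, Wnt target genes lay at 0.12 for CCICs against Non-CCICs and −0.16 for Colonospheres against Non-CCICs relative to random lists; the cause was not tested. In the last case the sign changed from 0.18, inside the random range both times. Among lists that stood apart, the sign changed for ribosomal protein genes in Colonospheres against Non-CCICs, which went to 0.14 with the length trend removed; these transcripts are short. Calls at the edge of the random range also moved. In Colonospheres against Non-CCICs, quantile normalization put TGF-beta and BMP response at percentile 1.53 and Wnt components at 2.82, summed records put ribosomal proteins at 4.65, and ERK output reached 1.99 with coding records and 2.09 with the length trend removed. In Colonospheres against CCICs, coding records put ERK output at 1.08 and p53 targets at 97.6. Of 60 recomputed counts, 32 stayed within 1.5 times, and of 741 recomputed list positions 706 moved by at most 1 SD of the random lists. Centring, scaling to the listed totals and TMM shift all genes of a library alike, so they cannot move a list relative to its random lists. The 706 thus include positions that were fixed in advance. Of 2744 recomputed gene differences, 1581 stayed within their counting interval, and no difference of at least 2-fold changed sign; smaller ones did in Colonospheres, RBM5 and MYC among them. No paired analysis was possible because each group has 1 library, and no library could be left out. The listing minimum of 100 reads in the highest library leaves genes with few reads in all 3 libraries outside the comparisons.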

Other observations

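Gene ontology terms given in the deposited table were scanned after the lists had been examined, so these groups were chosen after their values were seen. Among 1270 terms of 15 to 150 genes, the term digestion lay 0.94 above its random lists in Colonospheres against Non-CCICs and 1.56 above in Colonospheres against CCICs. Of its 20 genes, 9 and 11 were at least 2-fold higher relative to the library medians. ADM2 and UGT1A1 were at least 2-fold lower in both comparisons, and SLC15A1 against Non-CCICs only. TFF3, a mucosal repair peptide, had 5647 reads in Colonospheres, 93 in CCICs and 175 in Non-CCICs. The gastric protease gene CTSE had 2710 reads against 344 and 472, and the brush border protease gene MEP1A 773 against 113 and 211. TFF3, CTSE and MEP1A all lay below the expression floor. Of the colonocyte and goblet lists, outside this term, 2 genes below the floor were also chosen after their values were seen. The cadherin CDH17 had 8296 reads in Colonospheres against 83 in CCICs and 100 in Non-CCICs, and FCGBP, a protein of colonic mucus, 4425 against 321 and 387. The aldo-keto reductases AKR1C1 and AKR1C2 were higher by 4.07 and 2.78 against CCICs, but they share much of their sequence.

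The term anterior/posterior pattern specification lay 0.52 below its random lists in Colonospheres against CCICs. It holds 16 measured HOX genes, of which 10 were at least 2-fold lower relative to the library medians and 0 were at least 2-fold higher. Of the 10 lower genes, only HOXB3 and HOXB9 lay at or above the expression floor. HOXD13, among the 10, had a blank count in Colonospheres that was taken as 1. HOXB3 had 508 reads in Colonospheres and 1690 in CCICs, and HOXB9 1450 and 3820, while HOXA10 stood at 0.27. SHH, a morphogen, lay below the floor and had 116 reads in Colonospheres and 692 in CCICs. The term glucuronosyltransferase activity lay 1.59 below in Colonospheres against Non-CCICs, but 9 of its 15 records belong to the UGT1A locus, whose transcripts share their 3' exons. UGT1A1, UGT1A3 and UGT1A9 had 1440, 1431 and 1432 reads in Colonospheres, so the term describes 1 locus for the most part.

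Of the tests that follow, those on S phase, on polyadenylated histone variants, on RNA without poly(A) tails and on cycling in all phases were chosen only after the result was seen. The ribosomal protein and oxidative phosphorylation lists had medians below those of their random lists in CCICs against Non-CCICs. A candidate technical explanation is that short transcripts were recovered less well in the CCICs library. A trend with transcript length, fitted on genes outside each list, was removed. The ribosomal list then moved from −0.43 to −0.16 relative to its random lists and stayed under all of them. Most of the size thus went with this trend, which did not account for all of it. The random lists were not matched on length, so a steeper loss among the shortest transcripts could account for the rest. For the oxidative phosphorylation list the value moved from −0.34 to −0.10, at percentile 1.72, which is within 1 SD (0.05) of the edge of the random range, so length and a group difference cannot be told apart because too little of the difference was left. A difference between the sorted populations in translation or respiration genes stays open and untested.

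Replication-dependent histones were lower in Colonospheres than in CCICs. Length alone was argued against, since the list still stood at −1.94 relative to its random lists with the trend removed. Fewer cells in S phase may account for part of it, because the S phase list, whose transcripts carry poly(A) tails, lay at −0.64. The 8 polyadenylated histone variants lay at −0.63, but no prediction had been set for them, so no conclusion is drawn from them. Lower recovery of RNA without poly(A) tails may also contribute, since 26 small noncoding RNAs lay at percentile 0.38 of their random lists. Against Non-CCICs, where the histones were lower as well, they lay at percentile 0.04. Only 6 of these 26 RNAs lay at or above the expression floor, and their random lists were matched on expression but not on length. In CCICs against Non-CCICs, however, these RNAs lay at percentile 0.02, 0.34 below their random lists, while the histones lay above theirs, so histones did not follow untailed RNA there. Both explanations stay open, as does the growth condition, and the histone list lay a further 1.53 below the S phase list.

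The G2/M phase list lay above its random lists in CCICs against Non-CCICs. The list lay 0.76 above its random lists with the length trend removed, which argues against length. A larger share of cycling cells in all phases would move S phase genes as well. The S phase list stayed inside its random range, at percentile 77.6, while the histones, at 0.23, did lie above theirs. The G2/M list lay 0.73 further above its random lists than the S phase list. The SD of 0.09 for this gap is the spread of random lists only. It leaves out variation between libraries and among genes that vary together. How strongly each list responds to cycling was not measured, so the gap cannot decide against a larger share of cycling cells. A candidate explanation that stays open is that a gate on bright cells favours large cells late in the cycle; it was not tested, since the gate and the population are the same contrast. A difference in the cell cycle between the populations stays open as well, as a hypothesis.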
